A study of Homo sapiens and Mus musculus with 48 samples.

How the data were processed

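Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.7.9 and bedtools 2.25.0 and the genomes hg38 and mm10, with no role given to each. HEK293 total RNA was deposited by the authors as RPM, with 100% of values falling within 0.05 reads of whole multiples of a single read step and column sums of 439824.2 to 824599.5. HEK293 small RNA was deposited by the authors as RPM too, but its columns sum to 1139696.9 to 1514149.6, so its unit is called signal here. TC1 total RNA was deposited by the authors under a name of RPM too, but its values are whole numbers with totals of 55399 to 3078033, so it was read as an expected count per gene. A value of 0.01, written for 0, was set to 0. Codon usage was deposited by the authors as a ratio, and its values form a score per transcript, a z-score with mean 0 and SD 1 in each of 66 columns over 15423 transcripts. Samples other than the 8 of ribosome profiling were matched to columns by name, with 0 value columns left unmapped. Features whose names had been turned into dates were left out: 3 in HEK293 total RNA (at most 0.0064% of a library), 0 in small RNA and 26 in TC1 (at most 0.0511%).

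The comparisons, named-gene rule, lists and most alternatives were fixed before the data were examined, and others, such as DESeq2, edgeR on recovered reads and leaving out the shallow TC1 libraries, were added later. RNAs were kept at 1 RPM or more in 2 libraries, or 1 CPM or more in 3 libraries for TC1. HEK293 total RNA was rescaled by median of ratios, and small RNA was used on the deposited scale. Both were tested with limma (trend, moderated t) on log2(value + 0.5), which understates folds of low RNAs. limma had been designed for TC1 as well, but the values turned out to be counts, so edgeR quasi-likelihood tests with TMM scaling replaced it, and limma became an alternative. Printed TC1 levels are CPM over library totals. Adjusted p-values are Benjamini and Hochberg within each comparison, called below 0.05. The 4 FBL knockdown libraries carry 2 numbers, so they were averaged on the log2 scale in pairs by the first number, giving 2 replicates. Replicate numbers were not used for pairing, because residual correlations of libraries with the same number ran from −0.36 to 0.22 in HEK293 total RNA, 0 to 0.04 in small RNA and −0.15 to 0.26 in TC1. Codons were designed as log2 shares, but z-scores allowed only RPM-weighted means per library, over 15189 genes that hold 70.3% of mRNA reads. Fold changes are log2 unless written as -fold, and where a group held 0 reads the fold is a lower bound from a floor of 3 reads over the group.

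Named RNAs were SNORD97, SNORD133, FBL and DKC1, then per comparison up to 6 largest rises and 6 largest falls among those with adjusted p below 0.05, a mean of 5 RPM or CPM or more in the higher group, no overlap between the groups and an approved-style symbol, and up to 3 per list. For EB, Casr and the odorant receptors follow that rule, while the loci weighed at the end were chosen after their values were seen. Small RNA counts over copies of tRNA genes, antisense genes and paralogs cannot be assigned with certainty, so tRNA was also summed over 49 anticodons and 11 RNA classes. The fit gave every anticodon sum the same SE (0.157), pooled over anticodons, so its p-values do not measure the spread of any single anticodon.

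Gene lists numbered 17 for human and 24 for mouse and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The human lists cover ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation, mitochondrial genome mRNAs, translation factors, aminoacyl-tRNA synthetases, spliceosome, cell cycle, ATF4 targets, p53 targets, oxidative stress with methionine sulfoxide reductases, methionine and one-carbon metabolism, C/D and H/ACA RNP proteins, interferon-stimulated genes, extracellular matrix, neuronal genes, and morphogen and homeobox genes. The mouse lists cover pluripotent, germ layer, cardiac, muscle, vascular, blood, endoderm, trophoblast, germline, two-cell-like, imprinted, ectoderm and matrix programmes beside the shared housekeeping ones.

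The test code was tried first on simulated counts with planted changes. These were drawn around the mean of each RNA over all libraries with a common dispersion. In the HEK293 total RNA dKO design it gave 0 false calls of 26179 genes, in small RNA of the dKO 6 and of FBL knockdown 12, and in TC1 3 at mESC, 0 at EB and 2 at CM. Recovery of planted 4-fold changes was 92.5% under FBL knockdown, 37.3% at mESC and 41.8% at EB. Apart from planted changes the simulated libraries differed in depth alone, so these rates leave out differences in quality between real libraries. Arbitrary splits of the real libraries called up to 355 genes at mESC and 35 at EB. The alternatives covered scaling, filters, pseudocounts, tools, blocking, list tests, single libraries left out and the shallow libraries left out. Ribosome profiling (8 libraries) was not analysed here because no values per library were used, and a DKC1 knockdown named in the design had no samples and was not analysed here. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.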

Results

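The libraries came from HEK293, a human embryonic kidney line, and from TC1, a line of mouse embryonic stem cells. In HEK293 they covered WT cells, single knockouts of the C/D box small nucleolar RNAs SNORD97 and SNORD133, a double knockout (dKO) of both, and knockdown of FBL, the methyltransferase that C/D box RNAs guide. In TC1 they covered WT and Snord133 knockout cells as stem cells (mESC), as embryoid bodies (EB) and at the cardiomyocyte stage (CM). The series held 48 libraries in 20 groups. Total RNA of HEK293 was given as RPM for 2 libraries per group. Small RNA of HEK293, from inserts of 15 to 50 nt, was given as a signal on a similar scale for 2 libraries per group and 4 of FBL knockdown. All small RNA libraries were labelled as exposed to 250 µM sodium arsenite for 4 h. Total RNA of TC1 was given as read counts for 3 libraries per group, printed here as CPM of the library total. Listed reads in HEK293 total RNA were 1881218 and 1075032 in WT, 7094383 and 1024624 in the dKO, 519620 and 387815 in the SNORD97 knockout, and 697574 and 922182 in the SNORD133 knockout. The first dKO library held 63.4% rRNA and the other 7 from 5.5 to 13.5%. Small RNA libraries held 1734208 to 4991105 reads. TC1 libraries held from 55399 to 3078033 reads with a median of 1267118, and the shallow ones were mESC WT 1 (55399), mESC WT 3 (93596) and CM WT 2 (133133). The replicates are not stated to be separate cultures, so p-values measure only the spread between samples, which may be technical. Adjusted p-values come from limma for HEK293 and edgeR for TC1, and named genes followed a fixed rule on size, level and separation. Intervals on counts and floors of 3 reads cover counting error only.

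The first question was whether the targeted RNAs were missing from the edited HEK293 cells. SNORD133, an RNA guide listed among C/D box snoRNAs, stood at 28.4 and 4.09 RPM in the WT libraries and 18 and 34.9 in the SNORD97 knockout. It stood at 0.232 and 0 in the dKO and at 0 in both SNORD133 knockout libraries. The fall was called in the dKO (log2 fold change −4.03, SE 0.93, adjusted p 0.0441) and against the SNORD97 knockout (−5.06, adjusted p 0.00383). In the single knockout it was not called over all genes (−4.47, adjusted p 0.783). SNORD97 stood at 16.2 and 0 RPM in WT, 0 in both dKO libraries, 6.64 and 0 in the SNORD97 knockout and 28.5 and 9.95 in the SNORD133 knockout, and only dKO against SNORD133 knockout called it (−4.82, adjusted p 0.0273). The small RNA libraries measured SNORD97 better: 29.1 ± 0.424 (SD, n = 2) in WT, 1.48 ± 0.516 in the dKO (−3.93, SE 0.35, adjusted p 4.26e-11), 6.03 ± 1.6 in the SNORD97 knockout (−2.20, adjusted p 0.00017) and 40.8 ± 5.16 in the SNORD133 knockout (0.47, adjusted p 0.588). Without SNORD97 knockout library 2 the SNORD97 fall became −1.95 (adjusted p 0.0687). SNORD133 fragments reached 3 reads in each WT small RNA library and 0 in dKO and SNORD133 knockout libraries, at least 3.56-fold and at least 3.06-fold lower but not called (adjusted p 0.136 and 0.0914). FBL mRNA was 98.2 ± 19.6 RPM in WT and 46.4 ± 32.9 in the dKO (−0.65, adjusted p 0.62). DKC1, the pseudouridine synthase of H/ACA RNPs, was 20 ± 16.1 RPM in WT and 8.11 ± 7.2 in the dKO and was not called. Snord133 had at most 1 read in any TC1 library, so the mouse knockout could not be checked.

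**Figure D1:**
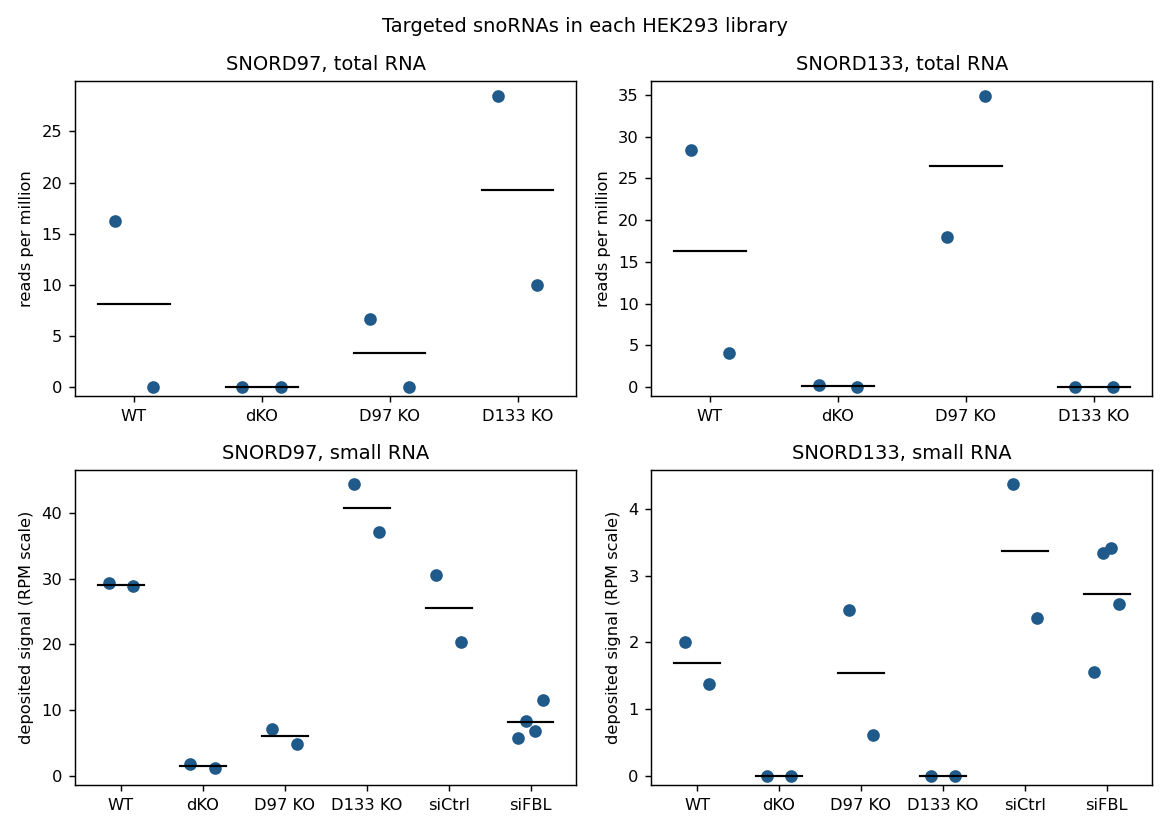
SNORD97 and SNORD133 in each HEK293 library, with RPM for total RNA and deposited signal for small RNA on the vertical axes and genotype or knockdown group along the horizontal axes. Each point is 1 library and each bar the mean of its group.

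The second question was which HEK293 total RNAs changed when both snoRNA genes were targeted. C2, a complement protease made mainly by liver and macrophages, rose from 4.42 ± 4.36 RPM in WT to 3860 ± 3140 in the dKO (9.68, SE 0.76, adjusted p 1.27e-06, n = 2 per group). MIR3681HG, a long non-coding RNA, rose from 0.234 to 129 ± 66.3 RPM (7.44, adjusted p 0.000169), and FUT11, a fucosyltransferase of the secretory pathway, from 8.77 ± 2.18 to 3040 ± 3920 RPM (7.09, adjusted p 0.000209). DUSP13, a dual-specificity phosphatase of testis and muscle (6.73, adjusted p 0.000465), the germline antigen gene MAGEB1 (6.29, adjusted p 0.00422) and H2BC1, a testis histone H2B (6.28, adjusted p 0.00196), also rose. HOXB8, a homeobox regulator, rose from 5.89 ± 2.27 to 92 ± 42.8 RPM (3.82, SE 0.6, adjusted p 0.00197), and HSPG2, which encodes the basement membrane proteoglycan perlecan, by 3.01 (adjusted p 0.0221). RABGGTB, a prenyltransferase subunit whose introns carry C/D box snoRNAs, fell from 12.2 ± 13.3 to 0.105 RPM (−3.85, SE 0.79, adjusted p 0.0192). The chromatin protein HMGB1 fell from 74.1 ± 56.4 to 8.98 ± 4.12 RPM (−2.81, SE 0.62, adjusted p 0.0303). The apoptosis and splicing factor BCLAF1 (−2.89, adjusted p 0.0117), the nuclear phosphoprotein NUCKS1 (−2.75, adjusted p 0.0167), and the recent duplicates NBPF20 (−2.85, adjusted p 0.00728) and NBPF19 (−2.70, adjusted p 0.00891), whose reads cannot be assigned with certainty, fell. The initiation factor EIF5B (−2.69, adjusted p 0.0255), the kinetochore protein CENPF (−2.40, adjusted p 0.0379) and the mitochondrial complex I subunits MT-ND6 (−2.73, adjusted p 0.028) and MT-ND4L (−2.82, adjusted p 0.0293) fell as well. Of 27220 RNAs tested, 212 were called, 179 higher and 33 lower, 137 of them mRNA and 70 lncRNA. edgeR on reads recovered from the RPM steps called 678. Without WT library 1 the count was 0, and C2 then stood at 8.63 (adjusted p 0.077, against a lowest of 3.33e-13 over the alternatives). Without WT library 2 it was 21. With 8-fold changes planted into simulated libraries, 4 of 66 genes (6.1%) were recovered and 0 of the 67 at 4-fold or at 2-fold, so absent calls carry little information in this design.

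Fixed gene lists in the dKO, tested by camera with a preset correlation of 0.01, moved in 2 directions. The mitochondrial genome mRNAs lay lower (0 of 13 positive, median −2.43, adjusted p 9.33e-16, or adjusted p = 0.413 with an estimated correlation), with 2 genes called and 10 when adjusted over the list alone. The lists for translation factors (adjusted p 1.35e-11), core spliceosome proteins (1.92e-11) and cell cycle (1.69e-10) lay lower, each with adjusted p = 0.43 with an estimated correlation. The same held for cytosolic ribosomal proteins (1.4e-11), nuclear-encoded oxidative phosphorylation (1.53e-08) and mitochondrial ribosomal proteins (1.08e-05), each with adjusted p = 0.462 with an estimated correlation. Aminoacyl-tRNA synthetases (8.03e-07) and ATF4 targets (2.32e-05) lay lower with adjusted p = 0.43 with an estimated correlation. Proteins of box C/D and H/ACA RNPs and tRNA 2'-O-methylation (0.000152) and methionine and one-carbon metabolism (0.00358) did so with adjusted p = 0.413 with an estimated correlation. Oxidative stress genes and methionine sulfoxide reductases lay lower too (0.0459, or adjusted p = 0.475 with an estimated correlation). Genes of morphogen and homeobox development lay higher (101 of 120 positive, adjusted p 0.000213, or adjusted p = 0.489 with an estimated correlation). Extracellular matrix genes lay higher with 54 of 59 positive (0.00026, or adjusted p = 0.462 with an estimated correlation). Neuronal genes (0.00868, or adjusted p = 0.462 with an estimated correlation) and interferon-stimulated genes (0.0288, or adjusted p = 0.465 with an estimated correlation) lay higher, and p53 targets were not called (0.445). The fry test, which asks whether genes of a list move one way on balance, called 0 lists, with adjusted p of 0.286 or more. Of the 16 lists called, 2 (ATF4 targets and mitochondrial genome mRNAs) kept the call without each library in turn, and without WT library 1 only these 2 were called. Without dKO library 1 the count was 11.

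The third question was what targeting each snoRNA gene alone did to HEK293 total RNA. In the SNORD97 knockout, mRNAs of cytosolic ribosomal proteins (camera adjusted p 4.17e-26), nuclear-encoded oxidative phosphorylation (1.84e-16), translation factors (1.53e-09), spliceosome proteins (8.84e-08), cell cycle (3.66e-07) and mitochondrial ribosomal proteins (6.17e-07) lay higher than in WT, each with adjusted p = 0.393 with an estimated correlation. Aminoacyl-tRNA synthetases and mitochondrial genome mRNAs (5.52e-05 each) and oxidative stress genes (0.00829) lay higher too. Methionine metabolism (0.021, median 0.003) did so only against other genes. These also had adjusted p = 0.393 with an estimated correlation. In the SNORD133 knockout the ribosomal list (2.47e-24), oxidative phosphorylation (2.06e-19), translation factors (1.7e-10), cell cycle and spliceosome (1.88e-09 each) and mitochondrial ribosomal proteins (3.22e-08) lay higher, each with adjusted p = 0.368 with an estimated correlation. So did mitochondrial genome mRNAs (9.95e-06), aminoacyl-tRNA synthetases (1.34e-05), oxidative stress genes (7.02e-05) and p53 targets (0.013), with adjusted p = 0.368 with an estimated correlation. In the SNORD97 knockout the test pointed up for p53 targets (0.123) and the ATF4 list (0.411) at medians of −0.06 and −0.15. Without WT library 2 the SNORD97 knockout called 0 lists. The SNORD133 knockout then called 4, of which p53 targets alone were among the 10, and the others were the ATF4 list, extracellular matrix and interferon-stimulated genes. limma called 0 individual genes in either knockout, against 1846 and 1524 at unadjusted p < 0.05, and edgeR on recovered reads called 35 and 25, all lower. limma called 2 genes in the SNORD97 knockout without SNORD97 knockout library 1. Between the 2 single knockouts limma called 0 genes, 666 had unadjusted p < 0.05, and edgeR called 1. Their folds correlated at 0.642 across genes, and dKO folds with them at −0.198 and −0.237. Simulations sharing WT libraries gave 0.407, 0.438 and 0.474 but lack the real WT spread, so a common effect was not tested.

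The fourth question was how the dKO differed from each single knockout in total RNA. C2 was higher against the SNORD97 knockout (11.99, adjusted p 2.63e-08) and the SNORD133 knockout (11.09, adjusted p 1.1e-07). FUT11 was higher by 7.86 and 7.89, and the neuronal phosphatase PTPRT by 7.85 and 7.54. The translational regulator CPEB3 (7.85, adjusted p 6.29e-05) and MIR3681HG (at least 81-fold) were higher than in the SNORD97 knockout, DUSP13 was at least 78.4-fold and at least 127-fold higher, H2BC1 at least 147-fold higher than in the SNORD133 knockout, and the photoreceptor channel subunit CNGB1 higher by 8.71 (adjusted p 5.43e-06). RABGGTB was lower (−4.73, adjusted p 0.00175, and −4.77, adjusted p 0.00178), as were the respiratory complex III subunit UQCRB (−4.56, adjusted p 0.00533, and −4.16) and the transcription coactivator SUB1 (−3.85 and −3.99). SSB, the La protein that binds nascent tRNA, fell to 2.05 from 34.1 RPM in the SNORD97 knockout (−3.79, adjusted p 0.00189), and the spliceosome core gene SNRPE fell by 3.84. The cap-binding factor EIF4E (−4.16, adjusted p 0.0147) and the mitotic gene HMMR (−3.94, adjusted p 0.00839) were lower than in the SNORD133 knockout. Calls numbered 3362 against the SNORD97 knockout (2633 higher, 214 of them tRNA) and 3278 against the SNORD133 knockout (2583 higher, 150 of them tRNA), and 1555 RNAs were higher and 532 lower against both. On the scale as deposited, the balance against the SNORD97 knockout turned to 764 higher and 1156 lower. Without dKO library 1 the 2 counts were 926 and 862, without dKO library 2 they were 2058 and 2109, without SNORD97 knockout library 2 the first was 189, and without SNORD133 knockout library 1 or 2 the second was 153 or 433. Rescaling moved the median of all RNAs from 0.17 to 0.81 and from 0.04 to 0.78 in these comparisons, and from −0.15 to 0.35 in the dKO, −0.21 to −0.35 in the SNORD97 knockout and −0.11 to −0.33 in the SNORD133 knockout against WT.

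Codon content of the expressed mRNAs was compared next, since SNORD97 and SNORD133 are studied here for tRNA methylation. AUG, the methionine codon, had an RPM-weighted mean z-score that differed from WT by −0.0439 in the dKO (SE 0.0733, adjusted p 0.593), 0.035 in the SNORD97 knockout (adjusted p 0.741) and 0.0765 in the SNORD133 knockout (adjusted p 0.963). limma called 0 of 61 codons in each knockout, with 11, 0 and 0 at unadjusted p < 0.05. Without WT library 2 the dKO called 20 codons.

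Small RNA of the dKO was compared with WT to ask which short RNAs changed under arsenite when both snoRNA genes were targeted. The clustered miRNAs MIR222 and MIR221, which target the cell cycle inhibitor p27, fell from 111 ± 11.8 to 10.3 ± 2.63 (−3.38, SE 0.31, adjusted p 4.26e-11) and from 101 to 9.47 (−3.34, adjusted p 4.26e-11). MIR671 rose (3.07, adjusted p 0.00297). Short fragments of the neuronal calponin TAGLN3 rose from 2.36 ± 1.4 to 15.6 ± 3.56 (2.56, adjusted p 4.38e-05), those of the ARF6 exchange factor PSD4 from 2.38 to 13.3 (2.27, adjusted p 0.000289), and those of the homeobox gene NKX2-8 by 2.33 (adjusted p 0.0183). Fragments of 3 genes fell: the mitochondrial PEP carboxykinase PCK2 (−2.85, adjusted p 0.00415), the stress gene GADD45B (−2.83, adjusted p 0.00868) and the adhesion molecule L1CAM (−2.70, adjusted p 0.0302). Of 17648 features, 148 rose and 180 fell, with 59 of 418 tRNA features lower, and 14 miRNAs higher and 3 lower. Summed over tRNA genes, 6 of 49 anticodons fell: Thr_TGT (−0.76, SE 0.157, adjusted p 9.81e-05), Cys_GCA (−0.72, adjusted p 0.000183), Thr_CGT (−0.57, adjusted p 0.00596), Val_CAC (−0.53, adjusted p 0.00992), Val_AAC (−0.50, adjusted p 0.0164) and Phe_GAA (−0.48, adjusted p 0.0195). After median-of-ratios rescaling 0 were called, and under quantile normalization 8 were higher and 8 lower, with the 6 named here still lower and all but Phe_GAA called, so the balance of calls depended on scale. Elongator Met_CAT (−0.07, adjusted p 0.734) and initiator iMet_CAT (0.15, adjusted p 0.545) were not called, though iMet_CAT rose under quantile normalization (0.29, adjusted p 0.0304). No sum over an RNA class was called (limma 0 of 11, 1 at unadjusted p < 0.05), though leaving out dKO library 1 or 2 gave 1 call. Without dKO library 1 or 2 the 328 calls became 162 or 185 and the anticodons 14 or 0, and without WT library 1 or 2 they became 78 or 114 and 2 each. With planted changes, 26.9% of 2-fold, 82.1% of 4-fold and 98.5% of 8-fold ones were recovered.

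The SNORD97 knockout was asked the same question in small RNA. The non-coding RNA AC110611.2 rose from 12.8 to 51.1 (1.99, adjusted p 7.43e-05), AC097652.1 by 3.26 (adjusted p 7.43e-05) and MIR4690 by 2.22 (adjusted p 0.0295). RN7SL, the RNA of the signal recognition particle, fell from 502 ± 7.39 to 273 ± 14 (−0.88, adjusted p 0.00168). Fragments of LINC00632, host of a circular RNA (−2.30, adjusted p 0.00408), of AC015813.1 (−2.55, adjusted p 0.0496) and of the elongation factor EEF1A2 (−2.10, adjusted p 0.0317) fell. Calls numbered 62, of which 56 were higher, 12 of them tRNA features and 6 miRNAs. The miRNA class rose by 0.45 (adjusted p 0.00679) and 7SK with 7SL fell by 0.23 (adjusted p 0.00679). Quantile normalization left 0 class sums called. Of 9 anticodons called, 8 rose, among them Lys_CTT (0.60, adjusted p 0.00437), and the other, Tyr_ATA, held at most 2 signal in any library. After median-of-ratios rescaling 1 was called. Met_CAT (−0.01, adjusted p 0.955) and iMet_CAT (0.10, adjusted p 0.697) were not called. AC110611.2 alone among the named RNAs kept its call without each library in turn. Without SNORD97 knockout library 1 or 2 the feature count fell to 22 or 12, and without WT library 1 or 2 to 24 or 41. The anticodon count in the same order fell to 1, 2, 0 and 1, and no class was called without SNORD97 knockout library 1 or without WT library 2.

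Small RNA of the SNORD133 knockout was compared with WT to ask which short RNAs depend on SNORD133. RNU7, the U7 RNA of histone mRNA processing, fell from 1480 ± 220 to 10.7 ± 2.28 (−7.05, SE 0.2, adjusted p 1.57e-32). The serine tRNA of mitochondria fell from 29000 ± 1430 to 657 ± 5.92 (−5.46, adjusted p 3.98e-31). Fragments of SNORD42A (291 to 4.21, −5.95, adjusted p 6.93e-28), SNORD29 (1200 to 26.8, −5.46, adjusted p 3.41e-29), SNORD48 (−5.34, adjusted p 5.52e-25) and SNORD78 (−5.29, adjusted p 9.55e-27) fell, all RNA guides of rRNA methylation. The non-coding RNA AL357033.1 rose from 10.6 to 177 (4.12, adjusted p 4.05e-14), and C9orf163 (3.62, adjusted p 1.49e-08), MIR7846 (3.54, adjusted p 6.11e-08) and fragments of the receptor kinase FLT3 (3.63, adjusted p 0.000391), of FAM83F (3.59) and of the growth factor binding gene IGFBPL1 (3.36, adjusted p 0.00175) rose. IGFBPL1 lost its call without SNORD133 knockout library 1 (adjusted p 0.0543) or WT library 2 (adjusted p 0.0721), and the other named RNAs kept theirs. Of 722 calls 359 were higher. Among 162 C/D box snoRNAs 29 fell and 10 rose, among 272 miRNAs 29 rose and 10 fell, and of tRNA features 68 rose and 132 fell. By annotated length, 20 of 32 C/D box snoRNAs shorter than 70 nt fell (median −2.20), against 6 of 59 from 70 to 79 nt (median −0.09) and 3 of 70 longer ones (median 0.02). Anticodon sums rose for 17 and fell for 16 of 49, the 6 largest being Ile_AAT (−1.98, adjusted p 9.19e-28), Arg_TCT (1.57, adjusted p 6.17e-19), Thr_TGT (−1.54, adjusted p 1.42e-18), Ile_GAT (−1.49, adjusted p 9.21e-18), Cys_GCA (−1.29) and Lys_CTT (1.22). All 49 shared the pooled SE of 0.157, so these p-values do not measure the spread of each. Met_CAT was not called (−0.07, adjusted p 0.688) and iMet_CAT rose by 0.35 (adjusted p 0.0428, and from 0.00466 to 0.464 over the alternatives, the highest after median-of-ratios rescaling). Its call was lost without SNORD133 knockout library 2 (adjusted p 0.222), WT library 1 (0.195) or WT library 2 (0.105). Over RNA classes, mitochondrial tRNA fell by 1.86 and miRNA rose by 1.22 (adjusted p 3.83e-06 each), snRNA fell by 0.30 (adjusted p 0.0486), 6 other classes rose, and C/D box snoRNA was not called (−0.33, adjusted p 0.147, and 0.000355 to 0.448 over the alternatives). Quantile normalization ended the calls of snRNA (−0.14, adjusted p 0.275) and rRNA (0.04, adjusted p 0.189), median-of-ratios rescaling left 3 classes higher and 3 lower, and snRNA was not called without any 1 of the 4 libraries. Without SNORD133 knockout library 1 or 2, or WT library 1, calls fell to 407, 431 or 443. Rescaling moved the median of all features from 0.11 to −0.03.

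**Figure D2:**
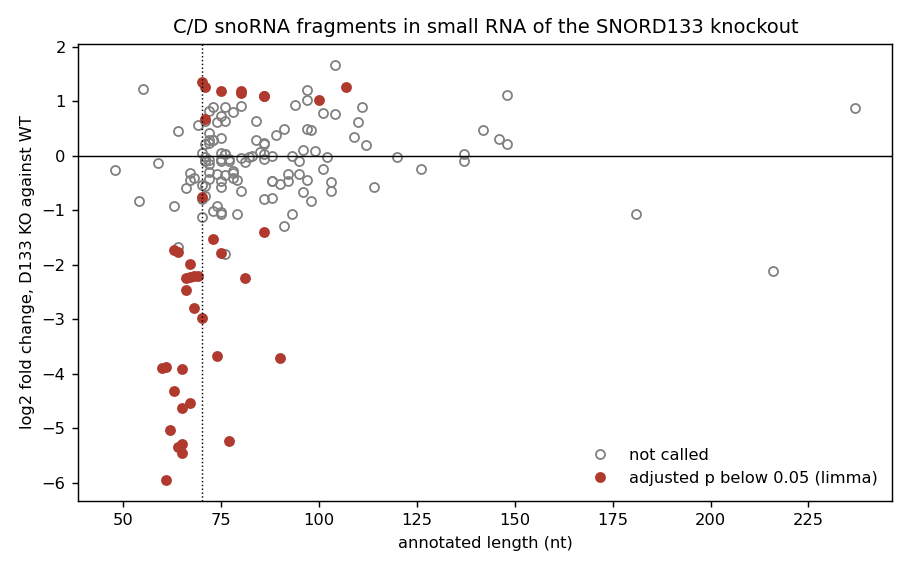
Annotated length of each C/D box snoRNA in nt on the horizontal axis against log2 fold change of its small RNA signal in the SNORD133 knockout on the vertical axis. Each point is 1 snoRNA, filled where limma gave an adjusted p below 0.05, and the dotted line stands at 70 nt.

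FBL knockdown was compared with control siRNA to ask which short RNAs depend on the C/D box methyltransferase. FBL fragments themselves rose from 11.6 ± 4.21 to 1690 ± 427 (7.14, adjusted p 5.95e-21), a length range in which the transfected duplex would also be read, so they do not show whether the mRNA fell. SNORD97 fell from 25.5 ± 7.21 to 8.12 ± 2.56 (n = 4 libraries in 2 pairs, −1.61, adjusted p 0.00265), but without control library 1 the change was −1.33 (adjusted p 0.0673). SNORD133 was 3.36 and 2.72 (−0.26, adjusted p 0.897). SNORD148 fell from 20.8 ± 1.65 to 2.05 ± 0.852 (−3.14, SE 0.33, adjusted p 5.21e-09), as did SNORD169 (−3.04, adjusted p 0.000121), C9orf163 (33.9 to 1.84, −4.00, adjusted p 1.09e-08) and DDIT4-AS1, antisense to a stress gene (−3.00, adjusted p 0.000121). Fragments of the aldehyde dehydrogenase ALDH3A1 (at least 9.15-fold, adjusted p 1.64e-06), the testis cytochrome oxidase subunit COX6B2 (at least 5.18-fold, adjusted p 0.00172), AC011503.1 (4.21, adjusted p 7.64e-08) and SPAG4, a sperm nuclear envelope gene (0.728 to 10.6, 3.45, adjusted p 2.36e-05), rose. CASD1, a sialic acid acetyltransferase (−2.93, adjusted p 0.0169), lost its call without control library 1 (adjusted p 0.0663) or knockdown library 1_2 (adjusted p 0.0777), and the other named features kept theirs. Of 770 calls, 484 were higher and 286 lower. Among C/D box snoRNAs 40 fell and 11 rose, and among tRNA features 203 rose and 1 fell. Anticodon sums rose for 37 of 49, including Ser_TGA (1.26, adjusted p 8.06e-13), Ile_GAT (1.23, adjusted p 1.55e-12), iMet_CAT (0.80, adjusted p 4.54e-06) and Met_CAT (0.44, adjusted p 0.0105), and 0 fell. Tyr_ATA was among the 37 (1.848, adjusted p 1.05e-24 under the pooled SE), although it held at most 2 signal in any library. Under quantile normalization of the features 8 rose and 7 fell, with iMet_CAT at 0.33 (adjusted p 0.0147) and Met_CAT at −0.12 (adjusted p 0.267), the highest of ranges that began at 3.48e-07 and 0.001, so a general rise of tRNA fragments depended on the scale. Class sums rose for 7SK and 7SL (0.50, adjusted p 5.93e-05), Y RNA (0.69, adjusted p 0.00188), mitochondrial tRNA (0.68, adjusted p 0.00414), H/ACA snoRNA (0.415, adjusted p 0.0055), snRNA (0.40, adjusted p 0.0211) and other RNA (0.256, adjusted p 0.00414), and fell for rRNA (−0.17, adjusted p 0.0395), while tRNA (0.25, adjusted p 0.0572) and C/D box snoRNA (−0.26, adjusted p 0.276) were not called. Quantile normalization left 0 class sums called, with 7SK and 7SL at −0.09 and snRNA at −0.07. Without control library 1 anticodons called fell to 16, and Met_CAT was not among them (adjusted p 0.134).

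**Figure D3:**
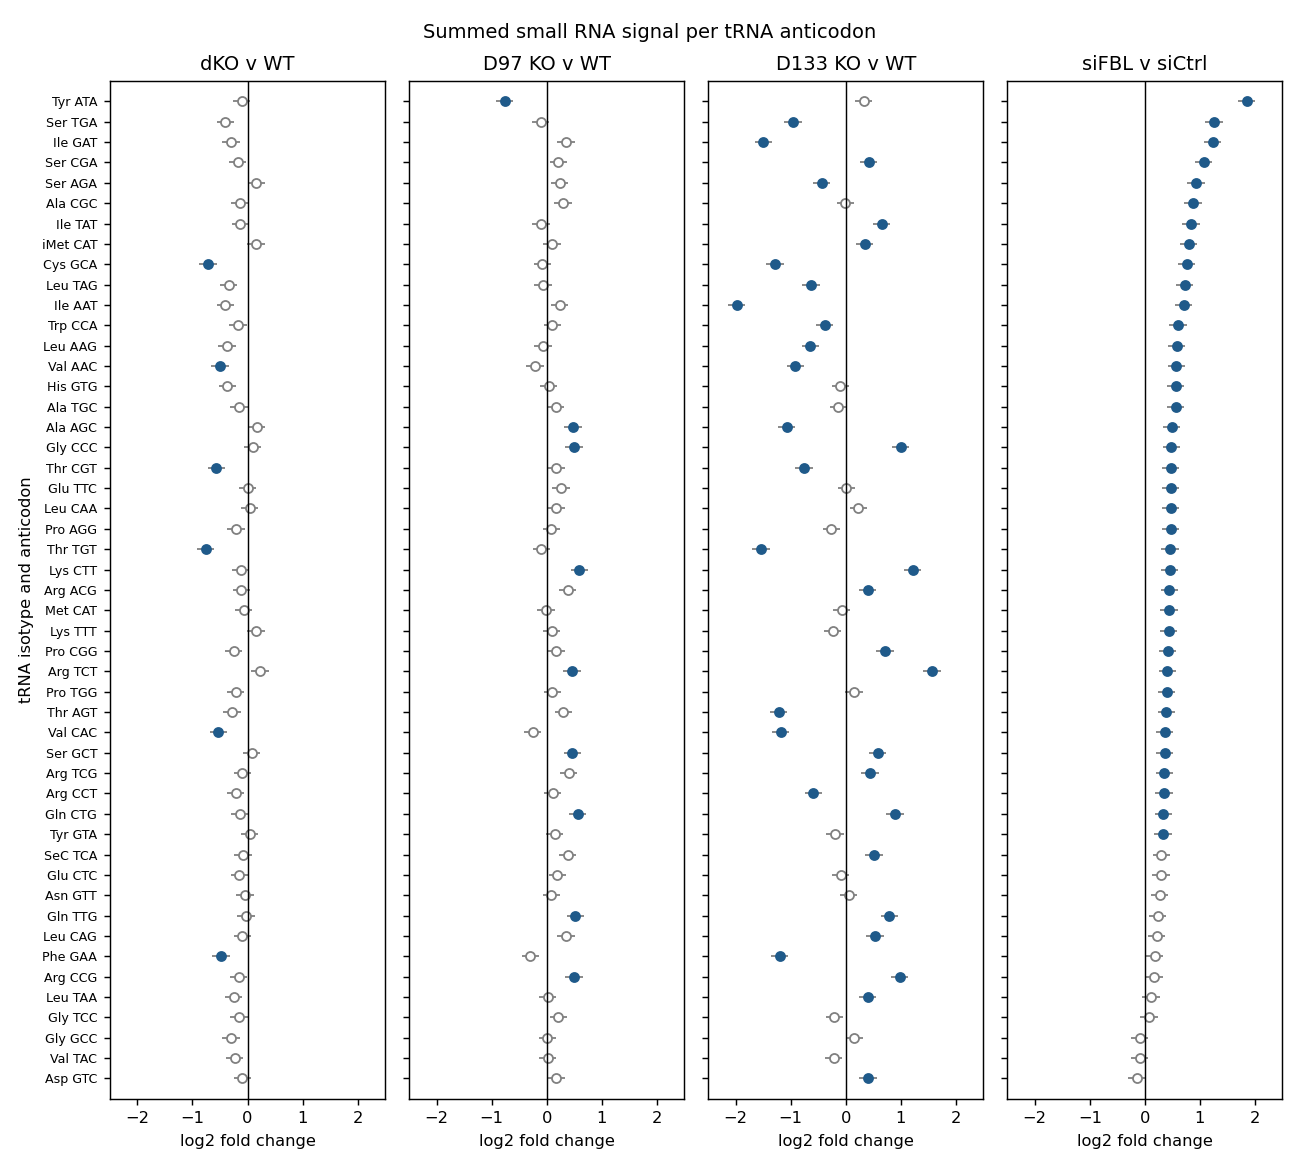
Log2 fold change of small RNA signal summed per tRNA anticodon, with anticodons on the vertical axis and 1 panel per comparison. Points are limma estimates with bars of 1 SE, filled where the adjusted p was below 0.05.

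The 3 knockouts shared WT small RNA libraries, so likeness was set against 20 simulations with that sharing but not the real WT spread. The dKO and the SNORD97 knockout correlated at 0.559 across features (0.591 simulated), the dKO and the SNORD133 knockout at 0.578 (0.613) and the 2 single knockouts at 0.514 (0.576). Covariance lay above the simulated one in each pair (0.317 against 0.246, 0.391 against 0.246 and 0.323 against 0.245). Features called in both were 24 higher and 1 lower in dKO and SNORD97 knockout, 84 higher, 78 lower and 6 opposite in dKO and SNORD133 knockout, and 44 higher, 0 lower and 1 opposite in the single knockouts. Sharing without changes gave means of 0.05, 0 and 0.05, calls being rare by construction, so overlap from sharing was not tested.

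Differentiation of WT TC1 cells was described first, as the ground for the knockout. From mESC to EB, genes of the two-cell-like state rose, including Zfp352 (at least 12.2-fold), Spopfm3 (at least 11.9-fold), Spopfm2 (at least 10.6-fold), members of a multicopy family, and Gm21761 (0.45 to 44.5 ± 5.47 CPM, 5.25, adjusted p 1.74e-06, n = 3). The germline transcription factor Taf7l rose at least 14.2-fold (adjusted p 2.5e-06), and the transporter Abcb5 at least 9.71-fold and the growth factor Fgf1 at least 7.82-fold. The epithelial keratin Krt19 rose from 0.563 to 44.5 CPM (4.96, adjusted p 6.88e-06), the imprinted genes Peg10 (3.49, adjusted p 0.00207) and Kcnq1ot1 (2.69, adjusted p 0.0208) rose, and so did the pacemaker channel Hcn4 (3.08, adjusted p 0.00254) and Snord97 (2.38, adjusted p 0.0149). The stem cell RNA Platr15 fell from 871 to 15.6 CPM (−4.97, adjusted p 1.86e-08), with the AKT coactivator Tcl1 (−4.62, adjusted p 0.000502), the cilium gene Ift46 (−4.54), Gtf2ird2 (−4.68), Mybpc3 (−4.39) and the photoreceptor factor Crx (at least 32.5-fold, adjusted p 0.00604). Calls numbered 1497, of which 1009 were higher and 488 lower. Of the lower ones 214 were tRNA features, in a comparison where mESC WT libraries 1 and 3 held 58.8% and 81% tRNA. The count was 968 or 841 without EB WT library 1 or 2, while limma on log2(CPM + 0.5) called 5413, of which 5243 were higher. Without mESC WT library 2, the only deep one, 30 of the 46 named genes lost their call. Of lists, two-cell-like genes (16 of 18 called higher, 17 when adjusted over the list alone, median 4.17, adjusted p 7.24e-24, or adjusted p = 0.027 with an estimated correlation) and imprinted genes (4 called, adjusted p 0.000102, or adjusted p = 0.409 with an estimated correlation) kept their call without each library, while germline genes (5 called, 2.72e-05, or adjusted p = 0.18 with an estimated correlation) did not. Cell cycle (3.13e-11, or adjusted p = 0.763 with an estimated correlation), naive pluripotency (9.72e-06) and mitochondrial ribosomal proteins (4.68e-06), both with adjusted p = 0.876 with an estimated correlation, lay lower. Oxidative phosphorylation (4.68e-06), spliceosome (0.00464) and translation factors (0.0102) also lay lower, with adjusted p = 0.973 with an estimated correlation. These lower lists rested on mESC WT library 2: without it oxidative phosphorylation (0.0205), spliceosome (0.00138) and translation factors (0.000291) were called higher, and cell cycle (0.961), naive pluripotency (0.442) and mitochondrial ribosomal proteins were not called.

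From EB to CM, WT cells gained lineage genes and lost pluripotency and two-cell-like genes. Embryonic globins rose from at or near 0 (Hba-x at least 769-fold, adjusted p 2.76e-18, Hbb-bh1 at least 465-fold and Hbb-y at least 306-fold, adjusted p 1.44e-18), as did the yolk sac thyroxine carrier Ttr (at least 103-fold), the leukocyte protein Plek (at least 49.8-fold) and the calcium binder S100g (at least 50.5-fold). The cardiac regulator Hand2 rose from 0.506 to 25.4 CPM (4.89, adjusted p 1.37e-08), the fibrillar collagen Col3a1 from 0.968 to 204 (6.99), the matrix gene Postn by 6.90, smooth muscle actin Acta2 from 0.769 to 109 ± 63.3 (6.28, adjusted p 1.76e-10) and the imprinted H19 from 41.4 to 5440 ± 1620 (6.20, adjusted p 8.1e-09). The endothelial cadherin Cdh5 rose at least 41.2-fold. Nanog, the pluripotency factor, fell from 38.9 to 0.6 CPM (−5.97, adjusted p 4.62e-09), with Fbxo15 (−6.48), Rex2 (−6.26), the germ cell gene Dazl (at least 30.5-fold), the keratin Krt7 (−6.24) and the sarcoplasmic regulator Pln (at least 52.4-fold). Among the largest falls were loci with few or no reads in CM libraries of either genotype, and these data do not settle whether they mark differentiation or the set of libraries. Casr, a calcium-sensing receptor, was at least 7050-fold lower, from 6520 ± 1060 CPM (adjusted p 2.45e-19), and the odorant receptors Olfr844 (−14.22), Olfr694 (at least 731-fold) and Olfr898 (at least 256-fold), the serpin Serpinb6d (at least 1130-fold) and the pheromone receptor Vmn1r13 (−13.52) were lower too. Calls numbered 4571 (1328 higher), and 2814 or 3038 without CM WT library 1 or 3. Of 69 named genes 55 kept their call without each library. The lists for two-cell-like genes (18 of 18 lower, adjusted p 1.4e-23), definitive and visceral endoderm (18 of 28 higher, 8.76e-17) and extraembryonic endoderm (13 of 16 higher, 1.96e-15) had adjusted p = 0.0201 with an estimated correlation. Blood (15 of 16 higher, 1.04e-16), fibroblast and matrix (12 of 25 higher, 7.28e-10) and germline genes (10 lower, 7.18e-07) had adjusted p = 0.0384 with an estimated correlation. Naive pluripotency lay lower (23 of 30, 2e-12, or adjusted p = 0.149 with an estimated correlation). Lists lay higher for cardiac progenitors (4.17e-08, or adjusted p = 0.0984 with an estimated correlation), cell cycle (4.88e-08, or adjusted p = 0.333 with an estimated correlation), endothelium (8.88e-05, or adjusted p = 0.157 with an estimated correlation), imprinted genes (0.000189, or adjusted p = 0.213 with an estimated correlation), neuroectoderm (0.000709, or adjusted p = 0.105 with an estimated correlation) and sarcomere (13 higher and 2 lower, 0.00191, or adjusted p = 0.316 with an estimated correlation). Scaling by TMM moved the median of all genes from 0.58 to −0.15 here, and from 0.04 to 0.27 from mESC to EB.

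In the Snord133 knockout at the mESC stage, the question was whether stem cells already differed. The placental homeobox gene Rhox5 (2.41, adjusted p 0.0377), the pluripotency-linked Pramel6 (at least 9.51-fold, adjusted p 0.00153), the glutathione-degrading Chac1 (at least 5.39-fold, adjusted p 0.0247), the neurofilament Nefh (2.66, adjusted p 0.00782), the neuronal tubulin Tubb3 (2.21, adjusted p 0.0336) and the Cdc42 effector Cdc42se2 (4.05, adjusted p 0.0334) were higher. Gtf2ird2, a general transcription factor paralog, fell from 192 ± 259 to 1.98 CPM (−5.37, adjusted p 6.57e-14). Calls numbered 160 with 12 higher and 116 of them tRNA features lower, in a comparison where mESC WT libraries 1 and 3 held 58.8% and 81% tRNA. The direction depended on the tool: DESeq2 called 396, of which 391 were lower, and limma on log2(CPM + 0.5) called 3536, of which 3515 were higher. Without mESC WT library 3 only 2 genes were called and without mESC WT library 2 there were 3077, and without knockout library 2 or 3 there were 72 or 70. Gtf2ird2 alone kept its call among 9 named genes, and Myc, called lower with all libraries (−5.73), turned to 2.18 without mESC WT library 3. Lists lay higher for ribosomal proteins (77 of 77 positive, 2.65e-30), translation factors (8.66e-17), spliceosome (1.38e-16), oxidative phosphorylation (3.98e-15), cell cycle (1.27e-13), naive pluripotency (1.59e-12) and mitochondrial ribosomal proteins (5.47e-06) and lower for two-cell-like genes (0.0156), with estimated correlations giving 0.311 to 0.324 and fry 0.0622 to 0.444. These libraries cannot separate the knockout from the poor quality of 2 WT libraries. Scaling moved the median of all genes from 0.3 to 0.21.

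At the EB stage the question was whether the knockout changed early differentiation. The BMP antagonist Nog rose from 0.828 to 12.7 ± 11.6 CPM (3.33, adjusted p 0.0298) and the inositol phosphatase Inpp5a from 3.9 to 67.6 ± 57.1 (3.70, adjusted p 4.16e-05). Ebf2, a transcription factor of brown fat and neurons, fell from 180 ± 52.8 to 28.1 ± 12.9 CPM (−3.08, SE 0.58, adjusted p 0.000373), and Olfr1441 from 33.1 ± 13.6 to 4.4 (−3.32, adjusted p 5.22e-06). Slfn14, a ribosome-associated nuclease (−3.19, adjusted p 0.00946), Olfr741 (−4.57, adjusted p 0.000105), the phagocyte oxidase subunit Ncf4 (−3.57, adjusted p 0.0433) and the potassium channel Kcnk4 (132 ± 217 to 4.09 CPM, −5.54, adjusted p 9.38e-12) fell, but Kcnk4 stood at −1.15 (adjusted p 0.9) without EB WT library 1. Only Olfr1441 kept its call without each library. Of 45 calls by edgeR 43 were lower, against 46 calls by DESeq2 and 0 to 22 by limma. Calls ran from 13 without knockout library 2 to 67 without EB WT library 3. They reached 181 without libraries under 150000 reads and 211 (194 lower) in a 2-group fit. Two-cell-like genes lay higher (16 of 18 positive, median 0.60, 1.75e-05, or adjusted p = 0.101 with an estimated correlation, fry 0.0158), with 0 called alone or over the list. Germline genes lay higher as well (0.00565, or adjusted p = 0.294 with an estimated correlation) but not without knockout library 2 (0.0513) or 3 (0.0632) or EB WT library 2 (0.113). Scaling moved the median of all genes from 0.33 to −0.02.

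At the CM stage the question was whether losing Snord133 altered heart differentiation. Myh6 and Myh7, the cardiac myosin heavy chains, were higher in knockout than in WT cells, at 329 ± 179 against 37.4 ± 34.4 CPM (3.13, SE 0.61, adjusted p 0.0011, n = 3) and 233 ± 109 against 37.2 ± 35.8 (2.63, SE 0.56, adjusted p 0.00482). Mybpc3, the cardiac myosin-binding protein, rose from 10.5 ± 3.61 to 47.6 ± 13.5 CPM (2.29, SE 0.52, adjusted p 0.0143), cardiac actin Actc1 by 2.08 (adjusted p 0.0186), and the smooth muscle genes Actg2 (1.29 to 12.3 CPM, 2.93, adjusted p 0.0245) and Tagln (18.7 ± 9.88 to 68.4 ± 18.9, 1.90, SE 0.47, adjusted p 0.0278) rose. Lefty2, a Nodal antagonist, rose from 0.8 to 16.8 ± 6.01 CPM (3.93, SE 0.81, adjusted p 0.00357), and the pluripotency gene Utf1 (3.43 to 25 ± 1.87, 2.55, adjusted p 0.0199) and the stem cell zinc finger gene Rex2 (0.6 to 13.3 ± 8.4, 3.93, adjusted p 0.0201) rose. The zinc finger genes Zfp980 (4.27, adjusted p 0.0138) and Zfp600 (3.81, adjusted p 0.0215), members of a repeated family, Serpinb6b (4.38, adjusted p 0.0186) and the carbonic anhydrase Car3 (at least 5.69-fold, adjusted p 0.0245) were also higher. Cubn, an endocytic receptor of visceral endoderm, fell from 339 ± 15.7 to 24.1 ± 16.8 CPM (−3.50, SE 0.57, adjusted p 1.01e-05), and Zic1, a neural transcription factor, from 61.9 ± 57.2 to 4.27 ± 1.01 (−3.05, SE 0.54, adjusted p 0.000121). The embryonic globin Hbb-bh1 fell from 380 ± 244 to 62.1 ± 35.4 CPM (−2.41, SE 0.58, adjusted p 0.0216), prothrombin F2 (−3.40, adjusted p 0.00378) and the gastric gene Gkn2 (−3.17, adjusted p 0.00482) fell, as did the forebrain RNA Dlx6os1 (−3.74, adjusted p 0.0373) and the coactivator Cited1 (45.2 ± 13 to 7.68, −2.30, adjusted p 0.00378). Fkbp6, a piRNA pathway protein, fell from 5.52 ± 1.76 to 0 (at least 8.5-fold, adjusted p 0.0213). Snord97 was not called (−0.20, adjusted p 1, 118 ± 56.6 CPM in WT and 74 ± 22 in the knockout). Of 23925 genes tested, 31 rose and 21 fell, and recovery of planted changes by edgeR was 1.5% at 2-fold, 49.3% at 4-fold and 92.4% at 8-fold. Other tools called fewer genes: DESeq2 18, limma 0 to 10 by the constant added and limma after quantile normalization 1, with Myh6 at adjusted p 2.08e-07 to 1 over the alternatives. Of 20 named genes, Cubn and Zic1 kept their call without each library. Without CM WT library 1 the 52 calls became 9, with Myh6 at 3.13 (adjusted p 0.0906), Myh7 at adjusted p 0.288 and Lefty2 at adjusted p 0.597, and without CM WT library 3 or knockout library 1 or 2 they became 14, 22 or 9.

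**Figure D4:**
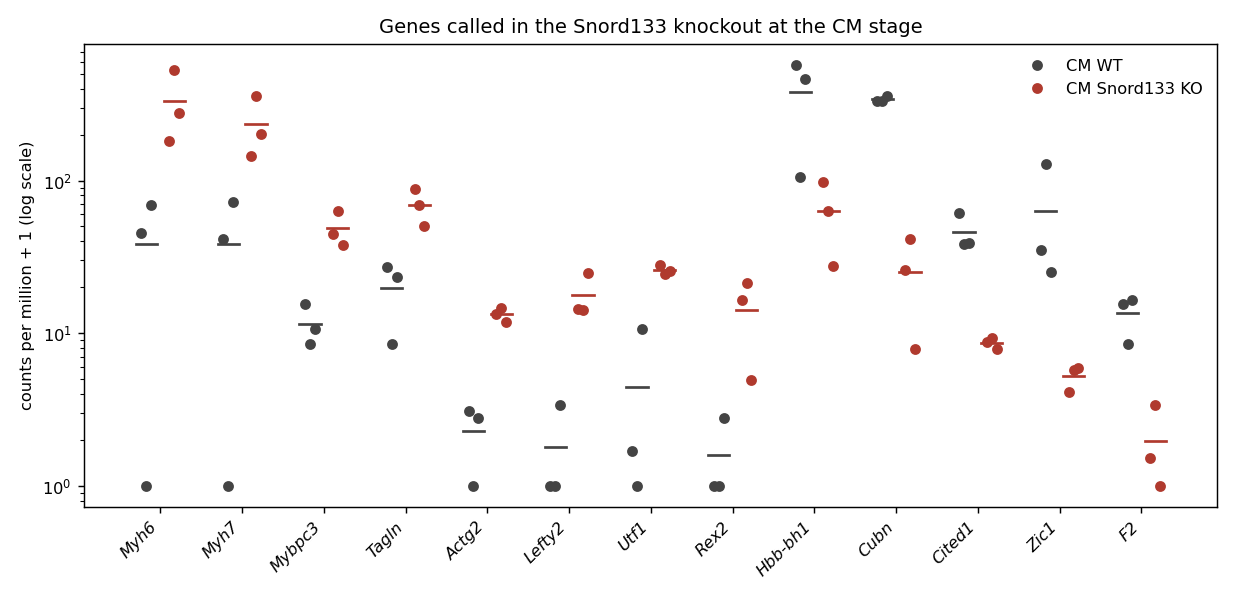
Levels as CPM plus 1 on a log scale for genes called at the CM stage, with genes along the horizontal axis and WT and Snord133 knockout side by side. Each point is 1 of 3 libraries per group and each bar the mean.

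Fixed lists at the CM stage gave the same picture across more genes. Sarcomere genes lay higher (29 of 31 positive, median 1.41, 5 called, 14 when adjusted over the list alone, adjusted p 1.22e-18, or adjusted p = 0.00577 with an estimated correlation, fry 0.000534). Smooth muscle genes (10 of 10 positive, 7 when adjusted over the list alone, 3.76e-11, or adjusted p = 0.000544 with an estimated correlation) and naive pluripotency genes (26 of 30 positive, 7.86e-11, or adjusted p = 0.145 with an estimated correlation) lay higher. Neuroectoderm (5 of 26 positive, 1.2e-10, or adjusted p = 0.00896 with an estimated correlation) lay lower. Blood (1 of 16 positive, 7.68e-10), extraembryonic endoderm (2.37e-07) and definitive and visceral endoderm (2 called lower, 6.78e-07) lay lower, each with adjusted p = 0.0632 with an estimated correlation. Fibroblast and matrix genes (1.08e-05) and primitive streak genes (0.000984) lay higher with adjusted p = 0.0632 with an estimated correlation. Trophoblast genes (0.000954, or adjusted p = 0.0343 with an estimated correlation) and formative pluripotency genes (0.00323, or adjusted p = 0.0924 with an estimated correlation) lay higher. Ribosomal proteins (7.69e-06) and cell cycle (0.00386) lay lower, both with adjusted p = 0.686 with an estimated correlation. Without knockout library 3 the ribosomal list (0.317) and cell cycle (0.347) lost their call, and without CM WT library 1 formative genes did (0.0959). Not called were endothelium (0.0976), surface ectoderm (0.161), spliceosome and skeletal muscle (0.266 each), cardiac progenitors (0.291), translation factors (0.472), mitochondrial ribosomal proteins and imprinted genes (0.571 each), germline (0.822), two-cell-like genes (0.948) and oxidative phosphorylation (0.161, whose test pointed down at a median of 0.031 and a mean of −0.001). Scaling moved the median of all genes from −0.1 to 0.09. Whether the effect differed between stages was tested as knockout effect in CM minus EB. Smooth muscle genes were higher (4.77e-06, or adjusted p = 0.0363 with an estimated correlation), as were naive pluripotency (1.71e-09, or adjusted p = 0.27 with an estimated correlation) and sarcomere genes (1.25e-06, or adjusted p = 0.176 with an estimated correlation), while neuroectoderm was lower (3.02e-05, or adjusted p = 0.137 with an estimated correlation).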

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

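A Dixon test was run on the called features of 74 groups of 3 or 4 libraries, where chance alone gives about 1 outlier in 20, and it marked 2 of them. COX6B2 fragments under FBL knockdown stood at 10.9 in library 2_1 against 3.63 to 4.68 in the other 3 (ratio 0.857). CASD1 fragments stood at 2.08 in library 1_1 against 0 in the other 3 (ratio 1), which is a level near a few reads. The number of outliers lies below what chance gives over 74 groups, and no library was removed because of them.

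Differences of the Snord133 knockout effect between stages were tested with edgeR. For EB minus mESC 8 genes were called (7 higher, 1 lower, 1387 at unadjusted p < 0.05), among them the transcription factor paralog Gtf2ird2 (5.08, adjusted p 0.0206) and the zinc finger gene Thap1 (4.04, adjusted p 0.0206). Gtf2ird2 and Thap1 both lost the call when 1 library was left out, and Thap1 turned to −0.64 without mESC WT library 1. Two-cell-like genes lay higher in this difference (1.3e-05, or adjusted p = 0.343 with an estimated correlation). Ribosomal proteins (1.52e-18), oxidative phosphorylation (2.34e-10) and naive pluripotency (2.87e-09) lay lower, each with adjusted p = 0.629 with an estimated correlation. Without the libraries under 150000 reads none of these 3 was called and ribosomal proteins turned higher (0.259).

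For CM minus EB 15 genes were called (12 higher, 3 lower, 1541 at unadjusted p < 0.05). The inner ear channel Tmc2 (7.61, adjusted p 0.000426), the stem cell RNA Platr10 (6.39, adjusted p 0.0491), the potassium channel Kcnk4 (6.25, adjusted p 0.00118), the cardiac small heat shock protein Hspb7 (4.61, adjusted p 0.0471), the focal adhesion protein Tns2 (4.55, adjusted p 0.00021) and the Nodal antagonist Lefty2 (4.30, adjusted p 0.0471) had a higher effect in CM, and Fkbp6 a lower one (−5.89, adjusted p 0.0471). None of these 7 kept its call without each library in turn, and the count ran from 1 to 11. limma on log2(CPM + 0.5) called 0 genes in both differences, and DESeq2 called 201 and 6.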

How the results depend on the processing

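Each choice was changed alone and the comparison rerun, except that quantile normalization of TC1 also replaced edgeR by limma, and that DESeq2 and edgeR on recovered reads brought their own scaling. Counts below read all called, then higher and lower in brackets where useful, and the cause of a difference was not tested unless the construction of the setting shows it. The camera test compares a list with the other genes of the same comparison, and fry compares it with no change. Depth sets what can be read at all: in HEK293 total RNA 3 reads stand for 0.349 to 3.609 RPM. Whether the low recovery of planted changes there comes from depth or from spread between replicates was not tested.

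Scaling was tried in 5 ways. Taking the HEK293 total RPM as deposited gave 1920 genes (764 higher, 1156 lower) in dKO against SNORD97 knockout and 1 between the single knockouts. For TC1, scaling by library totals alone gave 5 lists in the EB knockout and 188 genes (183, 5) for the knockout effect in EB minus mESC. Median-of-ratios rescaling of small RNA gave 0 anticodons in the dKO, 1 (0, 1) in the SNORD97 knockout and 1 class (1, 0) in the SNORD97 knockout. Quantile normalization gave 401 genes (230, 171) in the HEK293 dKO and, in small RNA, 99 features (67, 32) in the SNORD97 knockout and 460 (256, 204) under FBL knockdown. Applied to features before summing, it gave 16 anticodons (8, 8) in the dKO, 14 (11, 3) in the SNORD97 knockout and 15 (8, 7) under FBL knockdown, and 0 classes in the SNORD97 knockout and under FBL knockdown. It turned 7 sums of FBL knockdown: Arg_CCT −0.13, Arg_TCG −0.16, Gln_CTG −0.01, Met_CAT −0.12, Tyr_GTA −0.26, 7SK with 7SL −0.09 and snRNA −0.07, with adjusted p from 0.0554 to 0.952. In TC1, where the test also changed from edgeR to limma so that the 2 effects are not separated, it called 0 genes in the mESC knockout, 2 in the EB knockout, 1 in the CM knockout, 2254 (1570, 684) from mESC to EB in WT, and 0 in both differences between stages. Forcing 1 distribution on all libraries removes any general shift by construction.

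Fitting 2 groups alone gave 108 genes (105, 3) in the HEK293 dKO, 5835 (4290, 1545) in dKO against SNORD133 knockout, and in small RNA 51 (26, 25) in the dKO, 111 (82, 29) in the SNORD97 knockout and 5 (4, 1) under FBL knockdown. It called 27 anticodons (23, 4) in the SNORD97 knockout, and classes numbered 1 (0, 1) in the dKO, 10 (6, 4) in the SNORD97 knockout and 2 (2, 0) under FBL knockdown. In TC1 it called 12 (1, 11) in the mESC knockout, 211 (17, 194) in the EB knockout, 500 (400, 100) from mESC to EB, 3 (2, 1) for EB minus mESC and 25 (23, 2) for CM minus EB. Fewer residual degrees of freedom follow from the construction.

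Filters mattered for counts. With no filter the HEK293 dKO gave 139 genes (123, 16), dKO against SNORD97 knockout 1337 (1039, 298) and against SNORD133 knockout 1402 (1117, 285). Small RNA then gave 84 (39, 45) in the dKO, 22 (20, 2) in the SNORD97 knockout and 351 (261, 90) under FBL knockdown, and TC1 gave 32 (15, 17) in the CM knockout, 0 for EB minus mESC and 4 (3, 1) for CM minus EB. A filter of 5 RPM gave 2204 (1468, 736) in dKO against SNORD97 knockout and 4 classes (2, 2) in the SNORD97 knockout. A filter of 5 CPM gave 0 genes for EB minus mESC and 7 (6, 1) for CM minus EB. Restricting TC1 to mRNA and lncRNA gave 34 (6, 28) in the mESC knockout, 96 (61, 35) in the CM knockout and 16 (15, 1) for EB minus mESC.

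A pseudocount of 0.1 gave 61 genes (48, 13) in the HEK293 dKO, 1050 (773, 277) in dKO against SNORD97 knockout and 920 (693, 227) against SNORD133 knockout, and a pseudocount of 2 gave 342 (310, 32) in the dKO. edgeR on reads recovered from HEK293 total RPM called 678 (465, 213) in the dKO, 35 in the SNORD97 knockout, 25 in the SNORD133 knockout and 1 between them. Requiring an absolute log2 fold change of at least 1 left 0, 0, 10 (2, 8) and 4 (4, 0) anticodons in the dKO, SNORD97, SNORD133 and FBL comparisons, and 0, 2 (1, 1) and 0 classes in the last 3.

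Other tools for TC1 differed widely. DESeq2 called 396 (5, 391) in the mESC knockout, 18 (13, 5) in the CM knockout, 2412 (489, 1923) from EB to CM, 201 (190, 11) for EB minus mESC and 6 (6, 0) for CM minus EB. limma on log2(CPM + 0.5) called 3536 (3515, 21) in the mESC knockout, 1 in the EB knockout, 0 in the CM knockout, 5413 (5243, 170) from mESC to EB, 2454 (348, 2106) from EB to CM, and 0 in both differences. limma with 0.1 called 3712 (3707, 5), 0, 0, 5700 (5602, 98), 1738 (189, 1549), 0 and 0 in the same order. With 2 added it called 2569 (2515, 54) in the mESC knockout, 22 (2, 20) in the EB knockout, 10 (6, 4) in the CM knockout, 4485 (4236, 249) from mESC to EB, 1 for EB minus mESC and 0 for CM minus EB. Genes that edgeR called lower from mESC to EB turned positive under limma with 0.1, 0.5 and 2 added: Cox7a2 (2.59, 1.16 and 0.19) and Lsm7 (2.00, 0.72 and 0.04). With 0.1 and 0.5 added Cox6b1 (0.82 and 0.09), Mrpl53 (1.63 and 0.43) and Uqcrh (0.80 and 0.17) turned, and with 0.1 Rpl41 (0.39) and Tfap2c (0.23).

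Blocking by replicate number gave 3 genes in the mESC knockout (all lower), 16 (1, 15) in the EB knockout, 9 (3, 6) in the CM knockout, and 0 in both differences between stages. Crossing the numbers gave 574 (391, 183) in the HEK293 dKO. Treating the 4 FBL knockdown libraries as separate gave 1248 (742, 506).

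Lists were retested with an estimated correlation, which called 0 in each HEK293 knockout against WT, 0 in the mESC and EB knockouts, 4 (3, 1) in the CM knockout, 1 from mESC to EB, 6 (4, 2) from EB to CM, 0 for EB minus mESC and 1 for CM minus EB. The fry test called 0 in each HEK293 knockout, 0 in the mESC knockout, 1 in the EB knockout, 7 (6, 1) in the CM knockout, 4 from mESC to EB, 11 (8, 3) from EB to CM, 0 for EB minus mESC and 1 for CM minus EB.

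Leaving out the 3 TC1 libraries under 150000 reads gave 1 gene in the mESC knockout, 181 (13, 168) in the EB knockout and 5 (4, 1) for EB minus mESC. Lists then numbered 5 (4, 1) in the mESC knockout and 1 for EB minus mESC. In the mESC knockout ribosomal proteins turned lower (0.068), Mybpc3 moved to 0.92 and Myc to 2.16, and from mESC to EB Myc moved to 2.69. For EB minus mESC Thap1 moved to −1.86 and the lists for cell cycle (0.854), spliceosome (0.966), ribosomal proteins (0.259) and translation factors (0.372) turned higher. With 1 WT stem cell library left, these values rest on it.

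Leaving out 1 library at a time gave these ranges for HEK293 total RNA. The dKO called 0 genes without WT 1 to 202 (152, 50) without dKO 1, and 2 lists without WT 1 to 16 (4, 12) without WT 2. The SNORD97 knockout called 0 genes without its library 2 to 2 without its library 1, and 0 lists without WT 2 to 12 (11, 1) without WT 1. The SNORD133 knockout called 4 lists without WT 2, of which p53 targets alone were among its 10, to 11 without its library 1. dKO against SNORD97 knockout ranged from 189 (187, 2) without SNORD97 knockout 2 to 2311 (1877, 434) without SNORD97 knockout 1, and against SNORD133 knockout from 153 (151, 2) without SNORD133 knockout 1 to 2109 (1616, 493) without dKO 2. Codons in the dKO ranged from 0 without dKO 1 to 20 (9, 11) without WT 2.

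List values in the dKO ran from a lower direction without WT 2 to a higher one without WT 1 for ribosomal proteins (2.75e-29 to 0.061), mitochondrial ribosomal proteins (4.96e-11 to 0.59) and oxidative phosphorylation (9.21e-20 to 0.219). Oxidative stress genes were lower without WT 2 (3.51e-05) and without dKO 1 (0.695) and higher without WT 1 (0.143). In the single knockouts lists ran from higher without WT 1 to lower without WT 2. In the SNORD97 knockout these were cell cycle (1.4e-12 to 0.599), spliceosome (6.72e-17 to 0.0659), aminoacyl-tRNA synthetases (4.27e-08 to 0.797), mitochondrial genome mRNAs (4.35e-10 to 0.253), mitochondrial ribosomal proteins (2.98e-12 to 0.599), oxidative phosphorylation (2e-25 to 0.987), oxidative stress (3.5e-06 to 0.133) and translation factors (1.07e-18 to 0.133). In the SNORD133 knockout they were spliceosome (7.27e-18 to 0.0955), aminoacyl-tRNA synthetases (2.09e-08 to 0.983), ribosomal proteins (1.94e-38 to 0.605), mitochondrial genome mRNAs (1.99e-10 to 0.372), mitochondrial ribosomal proteins (1.05e-12 to 0.845), oxidative stress (9.45e-08 to 0.605) and translation factors (4.47e-19 to 0.15).

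In small RNA the dKO ran from 78 features (48, 30) without WT 1 to 185 (71, 114) without dKO 2, from 0 anticodons without dKO 2 to 14 (all lower) without dKO 1, and from 0 classes without WT 1 to 1 without dKO 1. The SNORD97 knockout ran from 12 features without its library 2 to 41 (37, 4) without WT 2, from 0 anticodons without WT 1 to 2 without its library 2, and from 0 classes without its library 1 to 2 (1, 1) without its library 2. The SNORD133 knockout ran from 407 (164, 243) without its library 1 to 580 (331, 249) without WT 2. FBL knockdown ran from 16 anticodons without control 1 to 37 without library 1_1.

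In TC1 the mESC knockout ran from 2 genes without WT 3 to 3077 (2650, 427) without WT 2, and its Myc from −6.70 without WT 2 to 2.18 without WT 3. The EB knockout ran from 13 (5, 8) without knockout 2 to 67 (2, 65) without WT 3, with 1 list without knockout 2 to 5 without knockout 1. The CM knockout ran from 9 (5, 4) without knockout 2 to 40 (24, 16) without knockout 3. From EB to CM the range was 2814 (786, 2028) without CM WT 1 to 4334 (1405, 2929) without CM WT 2. CM minus EB ran from 1 without CM knockout 2 to 11 (8, 3) without CM knockout 3. EB minus mESC ran from 0 without EB knockout 2 to 2239 (345, 1894) without mESC WT 2, with 4 lists (1, 3) without mESC WT 3 to 10 (2, 8) without EB WT 1, and Thap1 from −0.64 without mESC WT 1 to 6.68 without EB WT 3.

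From mESC to EB the range was 841 (552, 289) without EB WT 2 to 1920 (860, 1060) without mESC WT 3. Without mESC WT 2 as against another library, genes turned: Cox7a2 (−3.04 without mESC WT 3, 5.52), Lsm7 (−3.30 without EB WT 3, 5.07), Mrpl53 (−3.12 without EB WT 1, 4.00), Nid1 (−2.65 without mESC WT 3, 0.21) and Uqcrh (−4.39 without EB WT 3, 5.33). Myc ran from −6.25 without mESC WT 2 to 2.58 without mESC WT 3. Lists ran from lower without mESC WT 3 to higher without mESC WT 2 for cell cycle (3.19e-19 to 0.961), naive pluripotency (9.66e-15 to 0.442) and oxidative phosphorylation (1.51e-15 to 0.0205). Ribosomal proteins were higher without mESC WT 2 (1.85e-28) and lower without EB WT 1 (0.986). Spliceosome and translation factors were lower without mESC WT 3 (2.47e-09 and 2e-10) and EB WT 2 (0.0262 and 0.0674) but called higher without mESC WT 2 (0.00138 and 0.000291).

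For the rest, only values called with all libraries are counted, named genes and sums together. With 1 library left out, 1210 of 1685 gene values and 596 of 684 list values stayed called in the same direction. Genes and sums stayed called in 266 of 312 cases when a log2 fold change of at least 1 was required, 133 of 151 with a pseudocount of 0.1, 268 of 312 with blocking, 228 of 304 in 2-group fits, 87 of 91 with edgeR on recovered reads, 96 of 161 with DESeq2 and 87 of 161 with limma on log2(CPM + 0.5). Lists stayed called in 12 of 106 cases with an estimated correlation and 23 of 106 with fry. The alternatives written for ribosome profiling were not run because no values per library were used.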

Other observations

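The insert-length tests, the WT-library test, the tests of a uniform lead and of undifferentiated cells, and the split tests were chosen only after results were seen. The tests of loss from cells, of unspliced or genomic reads and of an outlying library were written earlier. Each CI below comes from resampling the genes or snoRNAs of a single fit. It therefore does not measure the spread between libraries, and it treats correlated genes as independent.

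At the CM stage the Snord133 knockout carried, by edgeR, more cardiac and smooth muscle mRNA (Myh6, Myh7, Mybpc3, Tagln) and less of visceral endoderm, blood and neural genes (Cubn, Hbb-bh1, Zic1). In HEK293 small RNA the SNORD133 knockout lost fragments of SNORD42A, SNORD29, SNORD48, RNU7 and the mitochondrial serine tRNA, and gained miRNA. Methionine tRNA sums and the AUG codon score were not called in the knockouts on the chosen scale. The exception was a small rise of iMet_CAT with SNORD133 loss that depended on scale and single libraries. In the dKO iMet_CAT was called only under quantile normalization.

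Fragments of C/D box snoRNAs fell in the SNORD133 knockout mainly where the snoRNA is short. The median fold of those under 70 nt lay 2.18 below that of longer ones (−2.18, CI −3.34 to −1.2), and at a border of 80 nt the gap was −0.46 (CI −0.83 to −0.21), which alone cannot tell. This may reflect fewer inserts from RNA shorter than 70 nt in these 2 libraries, a feature of library making, though the border of 70 nt was itself picked from the data. Loss of the snoRNAs from the cells cannot be told: in total RNA the lower snoRNAs had a median change of 0.51 (CI −0.17 to 0.76), but 25 of 29 were tested, near the floor (median WT 2.52 RPM or 7.5 reads). Whether mitochondrial tRNA, RNU7 and miRNA changes share the cause was not tested. The comparison by annotated length covered C/D box snoRNAs alone, and insert lengths were measured for no RNA.

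In HEK293 total RNA the dKO pattern lined up with a difference between the 2 WT libraries. Of the 1555 RNAs higher in the dKO than in both single knockouts, 84.2% (CI 82.3 to 86.2) were higher in WT library 2 than in WT library 1, against 65.2% of all genes, and 96.4% of the 532 lower ones were lower. The median difference between the WT libraries was 1.25 for the higher and −1.42 for the lower set, against 0.61 for all, and 177 of 179 and 32 of 33 of the dKO calls against WT lay in these sets. The call of lower housekeeping and higher developmental mRNA in the dKO might therefore be the same technical or culture difference that separates the WT libraries. C2 may stand apart, since its fold stayed at 8.63 without WT library 1 although its call was lost (adjusted p 0.077). Unspliced or genomic reads would favour long genes, and the correlation with gene span was −0.135 (CI −0.151 to −0.119), the other direction. What stays open is whether C2, FUT11 and HOXB8, whose folds far exceed the WT difference, reflect the 2 deletions or a property of the clone.

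The CM pattern did not come from the shallow or outlying library: without CM WT 2 and knockout 3 the sarcomere median was 1.36 (CI 0.87 to 1.91) and 49 genes were called. Camera then gave sarcomere genes adjusted p 1.72e-16, or 0.0137 with an estimated correlation, and fry 0.00498. A uniform lead in differentiation would raise blood genes, whose fall (median −1.07, CI −1.45 to −0.3) is part of the pattern, so it cannot tell. Naive pluripotency genes falling from EB to CM in WT were higher by 1.85 (CI 0.97 to 2.32), 22 of 23 positive, all 30 by 1.39 (0.7 to 2.23). Residual undifferentiated cells could explain that, since Pou5f1, Dppa5a and Nanog gained 9.7%, 6.8% and 3.7% of their mESC level, but 14 mRNA genes more abundant than Pou5f1 in mESC gained at most 0.4%, so this test cannot tell. Those 14 may mark the set of libraries rather than cells: Pcm1, chosen after its values were seen, had 23804, 33638 and 29300 reads in EB WT and 301, 14 and 275 in CM WT, and Casr and the odorant receptors lower at CM may belong with it.

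Regrouping the TC1 libraries asked how often arbitrary splits call as many genes. With 10 splits per comparison there are too few for a share under 0.05. The real CM grouping called 52 and the highest other split 8, the EB grouping 45 against 35, WT EB to CM 4571 against 7, and WT mESC to EB 1497 against 348 (1 of 10 splits each reached the real count, the real one). For the mESC knockout 4 of 10 splits did, with 355 against the real 160, which points to structure among the samples. For the difference EB minus mESC 27 of 100 splits called 8 or more (highest 179), so chance was not excluded, and for CM minus EB 4 of 100 called 15 or more (highest 17), a share under 0.05.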
